A study of Mus musculus with 6 samples.

How the data were processed

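Total RNA of the hippocampus was taken from 3 db/db and 3 db/m male mice of 18 weeks after behavioural tests, amplified, labelled with Cy3 and hybridised to 1-colour Agilent arrays, 1 mouse per array, per the labels. The arrays were scanned and read with Agilent Feature Extraction, whose version is 12.0.3.1 per the file headers and 10.7 per the submitters' processing notes, which also name limma.

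For each array the authors deposited the spot table of Feature Extraction. The processed signal is an intensity on a linear scale, background-corrected and not scaled between arrays, and the mean signal and median background signal are intensities too, per the file headers. Each array carried 176026 spots for 90752 probes of 60 bases, of which 85274 had 2 spots and 5478 had 1, and 4854 control spots. The authors also deposited a table of processed values for the same arrays, with scale and centring unstated. Set against the arrays, its values were on a log2 scale with nearly equal column medians of 5.66 to 5.67, so they had been normalized between arrays, while the method stays unknown. In it the columns named db/db replicates 2 and 3 held the values of each other's arrays (median absolute deviation 0.0095 and 0.0071 on the log2 scale against the other array). Both belong to the same group, so comparisons between groups do not depend on it, except with replicate number as a block.

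From the spot tables, log2 of the processed signal was taken and each array's 75th percentile over all non-control probes was subtracted, with no pseudocount. That percentile corresponded to intensities of 362, 381 and 369 on db/db replicates 1 to 3 and 331, 355 and 368 on db/m replicates 1 to 3. Control spots and spots with an outlier flag were left out, and spots of 1 probe were averaged. The median coefficient of variation between duplicate spots was 5.25% to 6.14% per array, and 0 spots were saturated. A probe was tested if it was well above background on all 3 arrays of at least 1 group, by at least 1 spot, which left 66939 probes, after 6 that outlier flags had left without a value on some array. A difference between dim probes is compressed by background, so its size is uncertain where a group was not well above background. Scaling to 1 percentile assumes that overall RNA output is alike, so a shift shared by most transcripts would not be seen.

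The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, without covariates), with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05. The labels name separate mice. Scores of principal components came from the same log2 values. Tables were read with the R package data.table (version 1.17.8) and figures drawn with matplotlib. The fit was tested on simulated data with 67 probes changed 2-fold, 67 changed 4-fold and 66 changed 8-fold among 66939, using the spread within slides. It recovered 52.2% of the 2-fold, 89.6% of the 4-fold and 100% of the 8-fold changes, with 7 false calls. With the measured slide shift added it recovered 44.8%, 86.6% and 90.9%, with 11 false calls. Most of the changed probes were 4-fold or 8-fold, and noise was drawn independently for each probe. The more probes truly change, the easier the adjusted threshold becomes, and 1 probe passed between db/db and db/m. These shares therefore do not give the power of that comparison.

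The files give each probe an ID and a sequence, with no gene name, transcript class or position, and the reference used here held gene names but no sequences. For this reason the analyses planned before the data were examined for the leptin receptor gene, for its neighbours, for long non-coding against protein-coding transcripts and for 42 gene lists, cell type markers among them, were not run, and neither were the alternatives on the probe that stands for a gene and on the window around the leptin receptor gene. The planned rule for naming genes by size and direction was kept only in its last part, the smallest unadjusted p in each direction, limited to 2 probes a direction. In place of the lists, probes were grouped after the files were seen by an exact match of at least 20 bases to consensus sequences of B1, B2, U6, U1, 5S and 7SK, on either strand. The consensus sequences were written from general knowledge and not taken from a database. Families with fewer than 10 tested probes, 7SK among them, were left out. The others were tested with camera at a preset and at an estimated correlation, and with limma's fry.

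Slide and scan were the same division of the arrays. Slide was run as a fixed block, as a random block and within slide 1, and slide 2 held db/m arrays only. Other alternatives were quantile normalization, normexp background correction with an offset of 50, the authors' log2 values, another set of probes behind the percentile, other filters on dim probes, replicate number as a block, a trended and robust prior, each array left out in turn and, added after the data were seen, centring within classes of probe GC content.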

Results

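Hippocampal RNA of 6 male mice aged 18 weeks was measured on single-colour Agilent arrays that carry 90752 probes for mouse transcripts. Of these mice, 3 were db/db and 3 were db/m. The db/db mouse carries a leptin receptor mutation on both chromosomes and becomes obese and diabetic, and the db/m mouse carries it on 1 chromosome and serves as the lean control. The series title gives the question as how long non-coding RNA levels in the hippocampus differ in obese, diabetic mice with impaired cognition. The files pair no probe with a gene name or a position, so transcripts are named here by probe ID, and probes are grouped by the RNA family whose sequence they hold. The number of probes well above background was 70464, 70170 and 68890 on db/db replicates 1 to 3, and 66957, 66527 and 69511 on db/m replicates 1 to 3. The arrays came from 2 slides, of which slide 1 held all 3 db/db arrays and db/m replicate 1, and slide 2 held db/m replicates 2 and 3. The number of arrays limits the precision of every comparison.

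A single probe, MOUSELNCRNA_44486, passed the test between db/db and db/m hippocampus, and its signal fell in db/db. Its log2 intensity relative to the array's 75th percentile was -1.65 ± 0.09 (SD, n = 3 mice) in db/db and 1.26 ± 0.06 (SD, n = 3 mice) in db/m. The log2 difference was -2.90 with a standard error of 0.0887, a 7.49-fold lower signal in db/db (limma, adjusted p = 0.000939), and all 3 db/db arrays lay below all 3 db/m arrays. The probe's sequence is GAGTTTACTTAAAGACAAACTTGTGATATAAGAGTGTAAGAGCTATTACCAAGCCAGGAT, and its 2 spots gave log2 differences of -2.91 and -2.90. With slide as a block the log2 difference was -2.87 with a standard error of 0.113 and no longer passed (limma, adjusted p = 0.107), and on slide 1 alone it was also -2.87 (limma, adjusted p = 0.594). Both fits rest on db/m replicate 1 as the only db/m array of slide 1, which is assumed to vary like the other arrays.

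The probes next in rank did not pass. MOUSELNCRNA_61680, measured by 1 spot, had a log2 intensity of -3.40 ± 0.14 (SD, n = 3) in db/db and -2.34 ± 0.09 (SD, n = 3) in db/m, a log2 difference of -1.06 with a standard error of 0.104 (limma, adjusted p = 0.185). The probes with the smallest p among those higher in db/db were MOUSELNCRNA_14976 and MOUSELNCRNA_4384, which were well above background on all 3 db/db arrays and on no db/m array. Set against a floor, their db/db signal was 1.79-fold and 2.01-fold that of db/m, with limma's adjusted p = 0.185 for each. These values set the db/db mean against the mean, per db/m array, of the higher of the probe's own signal and the lowest signal among probes well above background. For MOUSELNCRNA_4384 the floor was never reached, so its 2.01-fold is the fitted difference. Neither value is a lower bound. Under normexp background correction with an added offset of 50, which by itself shrinks differences between dim probes, and the 75th percentile, the log2 differences were 0.02 for MOUSELNCRNA_14976 and 0.06 for MOUSELNCRNA_4384 (adjusted p = 0.876 and 0.625), and with quantile normalization 0.09 and 0.13. The correction and the offset were not run apart. For MOUSELNCRNA_61680 the same settings gave log2 differences of -0.54 and -0.50. The 2 spots of MOUSELNCRNA_14976 disagreed on db/m replicate 1, at -5.50 and -7.54. The former lay above every db/db spot except that at -5.17 on db/db replicate 3. MOUSELNCRNA_4384 had 1 spot. Without db/m replicate 1 all of MOUSELNCRNA_61680, MOUSELNCRNA_14976 and MOUSELNCRNA_4384 passed, with adjusted p = 0.0164, 0.0106 and 0.0147 in limma.

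**Figure D1:**
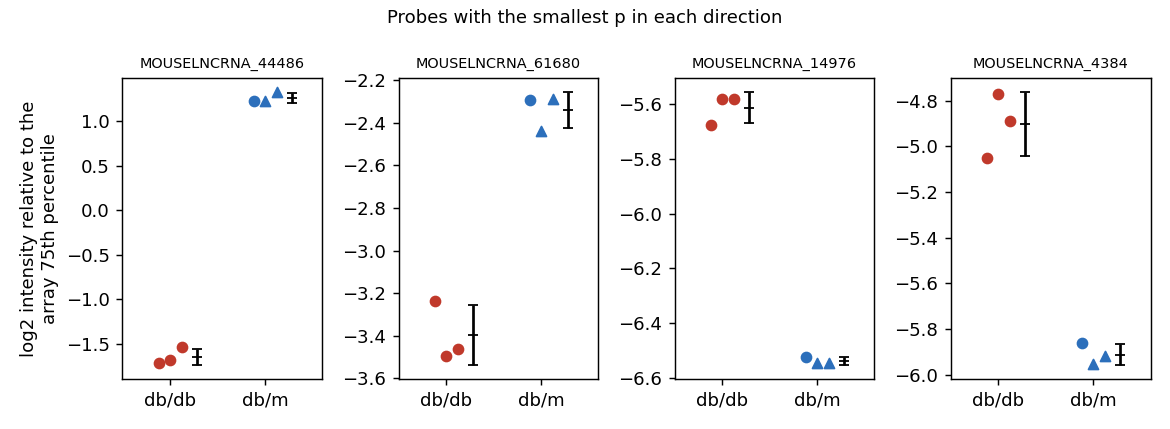
Log2 intensity relative to the array's 75th percentile of 4 probes on each db/db array (red) and db/m array (blue), with circles for slide 1, triangles for slide 2, and bars for the mean and SD of each group of 3. Each panel has its own vertical scale, and in each the 3 db/db arrays lie apart from the 3 db/m arrays, by a log2 difference of -2.90 for MOUSELNCRNA_44486.

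Probes that hold the strand opposite to the B1 and B2 repeats, or sequence of U1, had median log2 differences of -0.41, -0.41 and -0.33 between db/db and db/m, but none of these families passed at adjusted p = 0.231, 0.235 and 0.231 with an estimated correlation. B1 and B2 are short interspersed elements, repeats present in great number in the mouse genome, in introns and untranslated regions among other places. Among 82 probes that hold at least 20 consecutive bases of the strand opposite to the B1 consensus, the median log2 difference was -0.41, and 73 were lower and 0 higher in db/db at an unadjusted p under 0.05. Among 80 probes with the strand opposite to B2 the median was also -0.41, with 69 lower and 0 higher. U1 is the small nuclear RNA that recognises the start of introns in splicing. Of 37 probes with sequence of U1, 25 were lower and 0 higher, with a median of -0.33. For every family here, whether its probes measure the family's own RNA or other transcripts that hold such a stretch was not tested. In opposite-strand B1, opposite-strand B2 and U1 the median of every db/db array lay below that of every db/m array, and none of their probes passed adjusted over all probes tested. Adjusted over the list alone, 71 of the B1, 69 of the B2 and 22 of the U1 probes passed, but the families were chosen after the files were seen, and probes of a family share sequence and so repeat one measurement rather than add independent ones.

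Set against all other probes by limma's camera with a preset correlation of 0.01, the 3 families had adjusted p = 5.2e-28 for opposite-strand B1, 2.5e-25 for opposite-strand B2 and 1.4e-14 for U1. With a correlation estimated from the arrays none of them passed, at adjusted p = 0.231 with an estimated correlation for B1, 0.235 for B2 and 0.231 for U1. Limma's fry, fitted without slide, gave unadjusted p = 0.0181 for opposite-strand B1, 0.0353 for opposite-strand B2 and 0.0103 for U1. With slide as a block the median log2 differences were -0.24 for opposite-strand B1, -0.15 for opposite-strand B2 and -0.18 for U1.

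The 219 probes with same-strand B1 sequence had a median log2 difference of -0.09, and 26 were lower and 0 higher in db/db at an unadjusted p under 0.05. The 422 probes with same-strand B2 sequence had a median of -0.10, with 79 lower and 0 higher. Camera's adjusted p with the preset correlation was 1.1e-08 for same-strand B1 and 4.5e-13 for same-strand B2, and neither passed with an estimated correlation (adjusted p = 0.231 for both). Limma's fry, fitted without slide, gave them the smallest unadjusted p of the families, 0.00143 for same-strand B1 and 0.000939 for same-strand B2. The medians of these same-strand families with slide as a block were -0.11 and -0.10, and under quantile normalization they shrank to -0.019 and -0.029. The difference between same-strand and opposite-strand probes was not tested. Their brightness was unlike: median log2 levels per array were 7.36 to 7.50 for same-strand B1 and 7.55 to 7.67 for same-strand B2. On the opposite strand they were 1.03 to 1.57 for B1 and 0.03 to 0.55 for B2. Whether brightness alters the size of a difference here was not tested. None of the same-strand B1 or B2 probes passed, either over all probes or adjusted over the list alone.

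The 69 probes with sequence of 5S ribosomal RNA, a component of the large ribosomal subunit, had a median log2 difference of -0.24, with 4 lower and 0 higher. With slide as a block, however, the median turned to 0.09, and without db/m replicate 1 it was -0.43. For 5S camera gave adjusted p = 1.9e-08 with the preset correlation and adjusted p = 0.466 with an estimated correlation. The 214 probes with sequence of U6, a small nuclear RNA of the catalytic core of the spliceosome, had a median of -0.02, which turned positive under other scalings. Camera's adjusted p for U6 was 0.161 with the preset correlation and 0.781 with an estimated correlation. With the preset correlation U6 passed without db/db replicate 1 (adjusted p = 0.0101, median -0.04) and without db/m replicate 3 (adjusted p = 0.0439, median -0.02). Limma's fry gave unadjusted p = 0.268 for 5S and 0.369 for U6. None of the 5S or U6 probes passed over all probes or adjusted over the list alone.

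**Figure D2:**
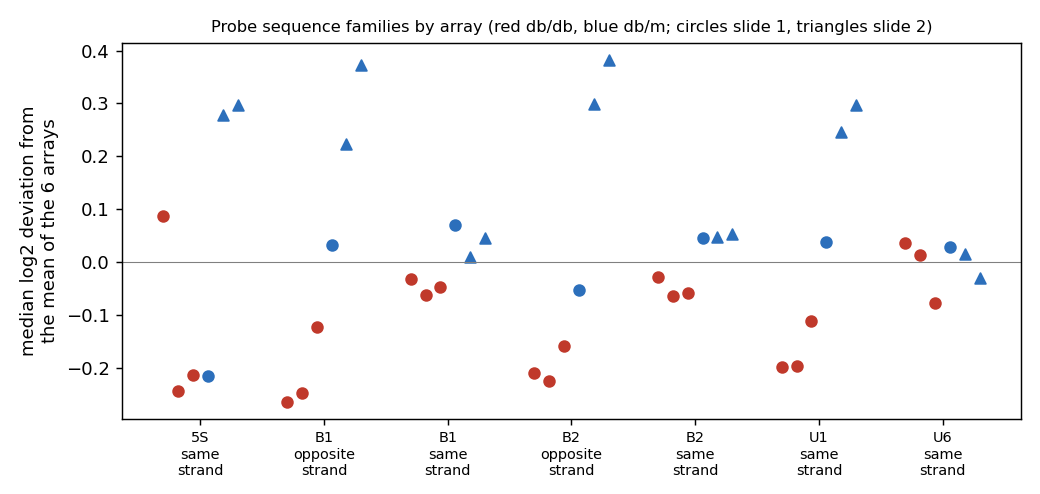
Median log2 deviation of each array from the mean of the 6 arrays (vertical axis) for 7 sequence families (horizontal axis), with db/db arrays in red, db/m arrays in blue, circles for slide 1 and triangles for slide 2. For opposite-strand B1 the db/db medians lie from -0.26 to -0.12, db/m replicate 1 at 0.03, and db/m replicates 2 and 3 at 0.22 and 0.37, while for 5S db/m replicate 1 lies at -0.22; the direction turned with slide as a block for 5S and under other scalings for U6.

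Over all 66939 probes tested, limma called 0 probes higher and 1 lower in db/db at an adjusted p under 0.05, and 4345 higher and 7636 lower at an unadjusted p under 0.05. The total of 11981 is 17.9% of the probes, where 3347 would be expected with no effect. Of these, 203 were at least 2-fold higher and 358 at least 2-fold lower in db/db. This balance kept its direction under each scaling, filter and prior, GC centring and the replicate block, but turned under some other fits. It turned to 379 higher and 114 lower with slide as a fixed block and 370 and 120 within slide 1, which are the same contrast of the db/db arrays with db/m replicate 1 alone, and to 237 and 159 with slide as a random block. It also turned without db/m replicate 3 (286 and 184) and without db/db replicate 1 (379 and 328). Without db/m replicate 1 it kept its direction at 209 and 849, as it did without each of the remaining arrays. Among the scalings that kept it, normexp with the offset gave 45 and 90 with the 75th percentile and 48 and 83 with quantile normalization. The 3 db/db arrays lay above the 3 db/m arrays for 6270 probes and below them for 10079, together 24.4% of probes, where chance gives 10%. With slide as a block 0 probes passed in either direction and 7156 had an unadjusted p under 0.05, and within slide 1 these counts were 0 and 5483. Without db/m replicate 1, 473 probes passed as higher and 4329 as lower in db/db.

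The first principal component held 41.5% of the variance between arrays. Its scores were -44.0, -47.9 and -19.7 on db/db replicates 1 to 3, 3.6 on db/m replicate 1, and 52.2 and 55.8 on db/m replicates 2 and 3, which shared slide 2.

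**Figure D3:**
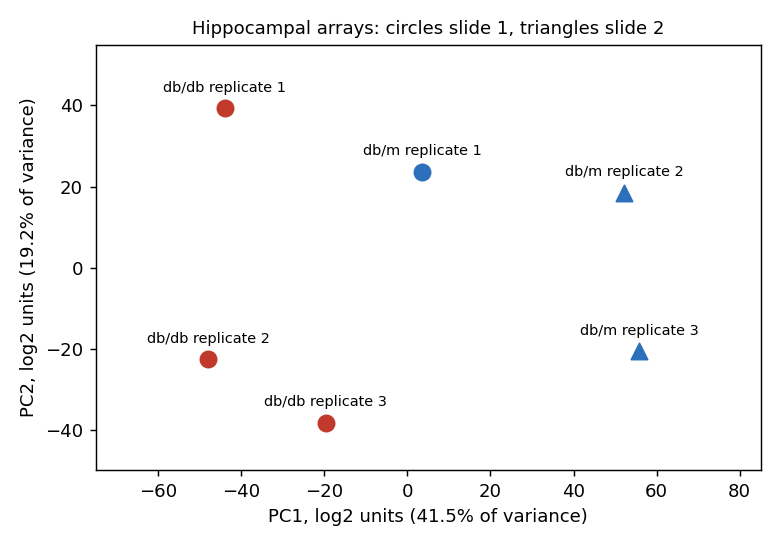
Scores of the 6 hippocampal arrays on the first and second principal components (log2 units, with the share of variance on each axis), db/db in red and db/m in blue, circles for slide 1 and triangles for slide 2. The db/db arrays lie at -47.9 to -19.7 on the first component, db/m replicate 1 at 3.6, and the db/m arrays of slide 2 at 52.2 and 55.8.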

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

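Of 25 control probes with ERCC or ETG names examined, 5 had over 50% of their spots well above background on every array, and these lay above the negative control spots, whose median intensity was at most 2.08 on any array. Other control probes exceeded 2.08 too without meeting that rule, the brightest being ERCC-00104_60 at 3.58 to 7.47. These spots enter no comparison, and no explanation was tested. As the mean over the 6 arrays of the median spot intensity, ERCC-00062_278 gave 211.7, ERCC-00028_121 gave 21.6 and ERCC-00012_90 gave 19.98. On the same measure ETG05_36762 gave 21.4 and ETG05_66023 gave 19.4.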

How the results depend on the processing

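Of 19 alternatives, the added ones (GC centring, and every alternative for the unadjusted count, the named probes and the families) were chosen after seeing the data. Counts of 0 higher and 1 lower were given by each scaling, filter, prior, GC centring and the random slide block. With slide as a fixed block and on slide 1 alone 0 probes passed, at any fold, and 7156 and 5483 had an unadjusted p under 0.05; each leaves fewer degrees of freedom. Leaving out 1 array gave 0 to 473 probes higher, 1 to 4329 lower, 1 to 752 changed at least 2-fold and 6690 to 16552 at an unadjusted p under 0.05. The upper ends came without db/m replicate 1; without db/db replicate 3, 2 passed as higher. The unadjusted count was 7254 without db/db replicate 2, 7576 without db/m replicate 2 and 6690 without db/m replicate 3. The unadjusted split of 4345 higher and 7636 lower became 6114 and 6964 under normexp with quantile normalization, 3917 and 9479 under normexp with the 75th percentile, and 4216 and 11161 with no filter on dim probes. The cause was not tested.

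With the replicate block 0 probes passed, at any fold, and 10831 had an unadjusted p under 0.05. The numbers do not pair the mice: deviations of same-numbered arrays correlated at 0.08, -0.15 and 0.13, and 2 of 6 arrays correlated best with their own number.

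MOUSELNCRNA_44486 stayed lower in all 19 alternatives (-2.96 to -2.42, adjusted p from 3.24e-05 to 0.594) and missed the threshold under 3: slide as a fixed block, slide 1 alone and the replicate block (adjusted p = 0.0656), while the random slide block kept the call (adjusted p = 0.00179). Opposite-strand B1 and B2 and U1 kept their direction in all 19, and so did same-strand B1 and B2. Not all 19 could change a difference, for the families or for MOUSELNCRNA_44486. The trended and robust prior and the replicate block leave it as it is, and slide as a fixed block and slide 1 alone are the same contrast. The 5S median was 0.0941 with slide as a fixed block and on slide 1 alone, and spanned -0.432 to -0.163 with 1 array left out. The U6 median was 0.0172 under quantile normalization, 0.0151 under normexp with quantile, 0.0178 in the authors' values, 0.0034 with the other percentile set and 0.0132 with GC centring, and spanned -0.0351 to 0.0168 with 1 array left out. The cause was not tested. Signal over background limits what dim probes show. Alternatives for gene-level results, the probe that stands for a gene and the window around the leptin receptor gene were not run, as probes have no gene names here.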

Other observations

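Over 3776 pairs of probes that share at least 30 bases on the same strand, the log2 differences between db/db and db/m correlated at r = 0.77 (Spearman's rho 0.74). Over 281 pairs that share at least 30 bases on opposite strands the correlation was r = 0.18 (rho 0.16). These correlations are across probes, which are not independent replicates, and their difference was not tested.

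More probes were well above background on all arrays of db/db and on none of db/m (311) than the reverse (14). Of the other splits into 3 and 3, db/db replicates 1 and 2 with db/m replicate 3 against the rest gave 296 and 8, so a count of this size was not particular to the db/db group.

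Of the tests below, that of GC content on the number of probes was set before its result was seen, and the tests of slide, of db/m replicate 1, of spots, of overlapping probes, of matched lists and of other splits were chosen after. The breadth of small differences between db/db and db/m, 11981 probes at an unadjusted p under 0.05, was compared with the other splits of the 6 arrays into 3 and 3, of which the highest gave 5789. Probes past the adjusted threshold numbered 1, a number that 2 of the 10 splits reached, the real one included, and the highest other split also gave 1; for the unadjusted count 1 of 10 splits, the real one, gave as many. With 10 splits the share is never under 0.1, which is too few to decide on chance.

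After centring within GC classes 11773 probes had an unadjusted p under 0.05, above the highest other split of 6056, which argues against a GC trend as the whole cause. Slide and genotype cannot be told apart for most of these probes. On the db/db slide, db/m replicate 1 shared 38.6% of the shift of db/m replicates 2 and 3. The db/db arrays put in its place shared -24.8% to 5.2%, but each was set against references that include db/m replicate 1. A high share for that array lowers theirs by construction. Their range is thus no independent reference, and the comparison rests on 1 array. The 4802 calls made without db/m replicate 1 may come in part from slide, since of the 15 splits into 4 and 2 the split by slide called 4149 probes and every other split 0. That split sets the same db/m replicates 2 and 3 against the db/db arrays, so it cannot part slide from genotype. On those probes db/m replicate 1 had a median position of 0.792, from 0 at the other db/m arrays to 1 at db/db. For 17.3% of them it lay beyond db/db, and for 3.37% beyond the other db/m arrays. This leaves an unusual mouse open, as it does a genotype difference. A db/db mouse under a db/m label is not settled either. MOUSELNCRNA_44486 was among the probes that passed without this array (log2 difference -2.92, limma, adjusted p = 0.00966), and it missed the threshold under 3 of the alternatives. On this probe the array read 1.22, beside 1.23 and 1.33 on db/m replicates 2 and 3 and -1.71 to -1.54 on db/db. MOUSELNCRNA_61680, MOUSELNCRNA_14976 and MOUSELNCRNA_4384 also placed it with db/m. All 4 probes were ranked with this array included, which favours that placing, and 4 probes do not settle it.

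For MOUSELNCRNA_44486 the tables argue against a faulty spot and, less firmly, against slide as the whole cause. On this probe db/m replicate 1 lay 31.1 SD of the db/db arrays above their mean although it shared their slide, and its log2 intensity of 1.22 was close to the 1.23 and 1.33 of the db/m arrays on slide 2. The probe was called with this array among db/m, however, so a wide gap was favoured by the choice. The SD rests on 3 arrays, and the gap on 1. Both of the probe's 2 spots separated all db/db from all db/m arrays. A sequence difference under the probe stays open, as 0 other probes overlapped it by at least 20 bases, and so does a lower level of its transcript in db/db, and the 2 cannot be told apart here.

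For the lower signal of opposite-strand B1 and B2 probes in db/db the tables argue against GC content and brightness. Over 10000 random lists of other probes matched on both, the middle value of the list medians was -0.0053 for B1 and -0.0032 for B2. The lowest was -0.15 for B1 and -0.13 for B2, against family medians of -0.41 for each, a gap of at least 0.264. Probes of a family correlate (estimated at 0.77 for B1 and 0.88 for B2) and those of random lists need not. The range of the lists therefore does not measure how far a family could vary by chance. Slide cannot be told apart from genotype. The median deviation of db/m replicate 1 was 0.0319 for B1 and -0.0525 for B2, and -0.0103 averaged over both families. In each family it lay between the db/db arrays and the db/m arrays of slide 2, and 1 array so placed does not decide. The lower signal of these opposite-strand probes did not pass in camera with an estimated correlation, while limma's fry gave unadjusted p = 0.0181 for B1 and 0.0353 for B2. It may be a genotype effect, a slide effect or both.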
